A study of Homo sapiens with 12 samples.

How the data were processed

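Ribosome footprints of HAP1 cells were measured in 12 libraries, 3 biological replicates in each of 4 groups. The group and replicate of each library were taken from the sample titles and the treatment recorded in the labels. Per the labels' protocols, cells were lysed with cycloheximide, lysates were digested with RNase I, ribosomes were pelleted through a sucrose cushion, and size-selected footprints were ligated to a linker, reverse transcribed, circularised and amplified by PCR. No molecular identifiers are described there.

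The authors deposited 1 table of RPKM values, reads scaled by transcript length and library total, for 19580 genes in the 12 libraries. Per the submitters' processing notes, reads were aligned with STAR 2.7.10a to hg38. The counting tool, annotation version and filters are not given in the sources used here. The table lists Ensembl identifiers with versions and no symbols, and 0 of them matched the gene table at hand, so no gene is named. A set of 23 gene lists (ribosomal proteins, stress responses, cell cycle, markers of other cell types and others) had been fixed before the data were examined, as were the comparisons, tests and named-gene rule. None of the lists could be tested without symbols. At most 2 identifiers that rose and 2 that fell are printed.

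Library totals, transcript lengths and whole reads were recovered from the RPKM steps, since each value is a whole number of reads divided by transcript length and library total. For each gene the smallest length in whole nucleotides that made all its positive values whole was taken. Such a length was found for all 15937 genes with a read. That 100% of positive values were then whole within 0.001 reads follows from the search. Multiples of that length would serve as well, so a gene with few reads may have been given too short a length. As a control, 1000 genes were drawn at random, leaving out genes read in few libraries and those with the longest transcripts. At totals moved by 1%, 0 of 1000 had such a length. At the totals found all 1000 had one, which the search had fixed in advance. Of the lengths, 34.2% were multiples of 3, so they hold untranslated regions and are called transcript lengths. On simulated data the step returned 12 of 12 totals and 99.98% of lengths and reads of the 14338 genes read in at least 3 libraries. The genes in the table held 99.9% of each total.

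Tests used limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend) on log2(RPKM + 0.5) with the deposited scaling. Genes with at least 1 RPKM in at least 3 libraries were kept, 11510 in all. One model of 4 group means over all 12 libraries, with 8 residual degrees of freedom, gave 6 contrasts, namely 5 pairwise comparisons and the interaction. Tests were two-sided with Benjamini-Hochberg adjustment within a contrast and a threshold of 0.05. With 3 libraries per group and 200 genes changed among the 11510, the same model was tested on simulated data. For 4SU+UVA against untreated it recovered 47% of changes of 1.5-fold, 79.5% of 2-fold and 90.5% of 4-fold, and called at most 0.09% of unchanged genes. For the interaction it recovered 24.5%, 64% and 92%, and called at most 0.10%. The simulation changed only these 200 genes and put in no shift by length or of the median gene. In the data 6796 genes passed for 4SU+UVA against untreated and the median gene moved, so these rates may not hold there.

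The rule for named genes took the largest rises and falls of 4SU+UVA against untreated (10 each had symbols been at hand, and 5 each for other contrasts) among genes with adjusted p under 0.05, a mean of at least 5 RPKM over the 12 libraries and no overlap between the libraries of both groups. The 2 highest and 2 lowest by log2 change were printed.

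After the table had been seen, genes were divided into 5 classes by transcript length and 5 by mean RPKM over the 12 libraries, and 14 classes per contrast were tested with limma's camera at a preset correlation of 0.01 and with an estimated correlation. The genes changed by UVA alone were followed in the other comparisons in the same way. A length slope per library was the regression of each gene's log2 difference from its 12-library mean on log2 length. Per-library measures were compared by exact two-sided permutation tests, over 20 regroupings for a pair of groups, which cannot give p under 0.1. The interaction of such a measure was tested, by a choice made after the data had been seen, by permuting the residuals of a model with only the single effects of 4SU and UVA (100000 resamples, two-sided, the difference divided by its standard error). On simulated data without an interaction this test called 4.9% of 1000 measures at 0.05. The lowest p it gave was 0.0023, shared by measures at -6.9 and at 14.7 times their standard error, so it does not rank them. The 8 measures adjusted over were the length slope (all genes, most and least abundant class, thinned), mean transcript length per read and 3 shares of reads. These shares were of the 10 genes with most reads and of the genes that rose or fell with UVA alone. The slopes overlap, and both UVA sets were picked on the UVA and untreated libraries, so the adjustment adds little. A second test regrouped all 12 libraries in 369600 ways, with the difference divided by its standard error or not. Such regroupings also move the single effects of 4SU and UVA. Counting intervals are exact 95% intervals. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

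Alternatives covered the pseudocount, the filter, median centring, quantile normalisation, a block for replicate number, the variance trend, separate fits per comparison, a 2-fold requirement and leaving out each replicate. Added after the data were seen were limma voom on the recovered reads, thinning of every library to the 1898709 reads of the smallest, and leaving out replicates for the correlations.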

Results

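Ribosome footprints were sequenced from HAP1 cells, a near-haploid human line derived from the KBM-7 leukaemia line. In ribosome profiling, RNase I digests the mRNA that ribosomes do not cover, and the protected fragments are counted per gene. Cells were left untreated, were given 4-thiouridine (4SU) at 5 uM for 18 h, were irradiated with UVA at 6 kJ per square metre and harvested after 30 min, or received both. 4SU is a uridine analogue that enters newly made RNA and forms covalent bonds with nearby protein when excited by UVA, so the combined treatment was the one designed to place RNA-protein crosslinks on mRNA. The 4 groups held 3 biological replicates each, 12 libraries in all. Depth was 3785480, 5278490 and 5832366 reads in the untreated libraries, 3991129, 4450172 and 4514227 with 4SU, 3358145, 5425688 and 4613701 with UVA, and 5526950, 1899854 and 3044856 with 4SU+UVA. Between 2 replicates of a group, log2 values correlated across genes at r of 0.986 to 0.993, and no pair looked like 1 library deposited again, since the 12 pairs gave a chi-square of 1.69 to 5.46 per gene against counting error alone. Only footprints were used here, so the values are footprint densities, which follow both the amount of an mRNA and its ribosome load. Fold changes are differences of mean log2(RPKM + 0.5), where the added 0.5 draws the log change of low genes toward 0, so they need not equal the ratio of mean RPKM.

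The study's central comparison set 4SU+UVA against untreated cells. Footprint density rose at 4674 genes and fell at 2122, together 6796 of the 11510 genes tested with 3 libraries per group (limma, adjusted p under 0.05). At least 2-fold changes were made by 735 rising and 335 falling genes. The genes that fell had longer transcripts, with a median of 3457.5 nt against 2242 nt for the genes that rose. Averaged over reads, the length of the transcript that a footprint came from was 3117 ± 14.9 nt (SD, n = 3) in untreated cells and 2791 ± 37.1 nt (SD, n = 3) with 4SU+UVA, a mean that fell by 326 nt, and every 4SU+UVA library lay below every untreated one (exact two-sided permutation test, p = 0.1, the smallest that 3 against 3 can give). The median gene rose by 0.23 on the log2 scale with the deposited scaling and by 0.03 after each library was centred on its median, which turned the split to 2846 higher and 3082 lower genes, and quantile normalisation gave 3011 and 2910. The direction of a small change therefore holds only relative to the median gene. RPKM is scaled to each library's own total, so large rises and falls are relative too. The values do not give the absolute number of footprints. The 3 libraries of each group did not overlap at 63.7% of genes, where chance gives 10%.

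**Figure D1:**
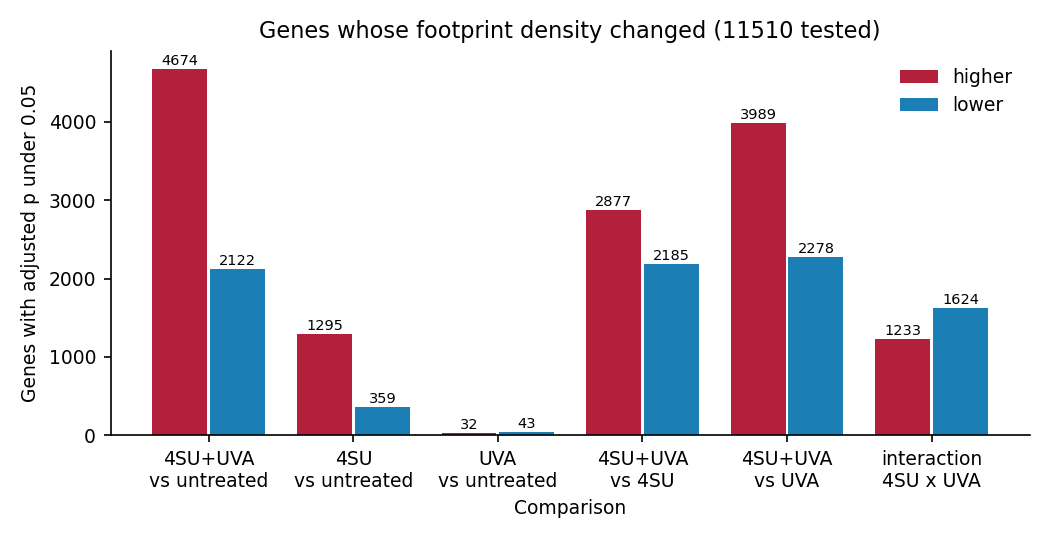
Number of genes whose footprint density was higher or lower (y axis, genes with limma adjusted p under 0.05 of 11510 tested) in each of the 6 comparisons on the x axis, 3 libraries per group. The combined treatment moved 4674 genes up and 2122 down, while UVA alone moved 32 up and 43 down; the up and down splits of the 5 pairwise comparisons change with the scaling, and under quantile normalisation UVA alone gives 22 and 20.

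The deposited table pairs its identifiers with no gene symbols, so 2 identifiers with large rises and 2 with large falls stand here for the 3143 rising and 1909 falling genes that met the rule for naming. Footprints on ENSG00000120738.8, with a transcript of 3137 nt, rose from 3.52 ± 0.435 RPKM in untreated cells to 272 ± 80.6 RPKM with 4SU+UVA (SD, n = 3 each), a 65.7-fold change (log2 6.04, SE 0.18, limma adjusted p = 1.9e-11). ENSG00000177606.8, 3257 nt long, rose from 6.04 ± 0.903 to 349 ± 87.4 RPKM, or 52.6-fold (log2 5.72, SE 0.17, limma adjusted p = 1.9e-11). Neither passed with 4SU alone, at 3.25 ± 0.129 and 6.04 ± 0.897 RPKM (limma adjusted p = 0.77 and 1). ENSG00000141367.12, 5292 nt long and abundant, fell from 323 ± 8.35 to 53.4 ± 1.4 RPKM, a 6-fold drop (log2 -2.59, SE 0.18, limma adjusted p = 4.9e-08). The largest fitted fall among the eligible genes, at the 99 nt ENSG00000288644.1, was -3.09 (SE 0.65, limma adjusted p = 0.001), from 8.67 ± 4.09 to 1.22 ± 2.11 RPKM, and it rests on 12 reads in the untreated and 2 in the 4SU+UVA libraries. The fitted value moved to -4.11 without 4SU+UVA replicate 1, which holds both of those reads, and to -4.61 and -2.45 with pseudocounts of 0.1 and 1. Per library read that is a ratio of 0.237 with an exact 95% interval of 0.0258 to 1.07. Such intervals cover counting error only, since reads amplified by PCR are not independent molecules.

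**Figure D2:**
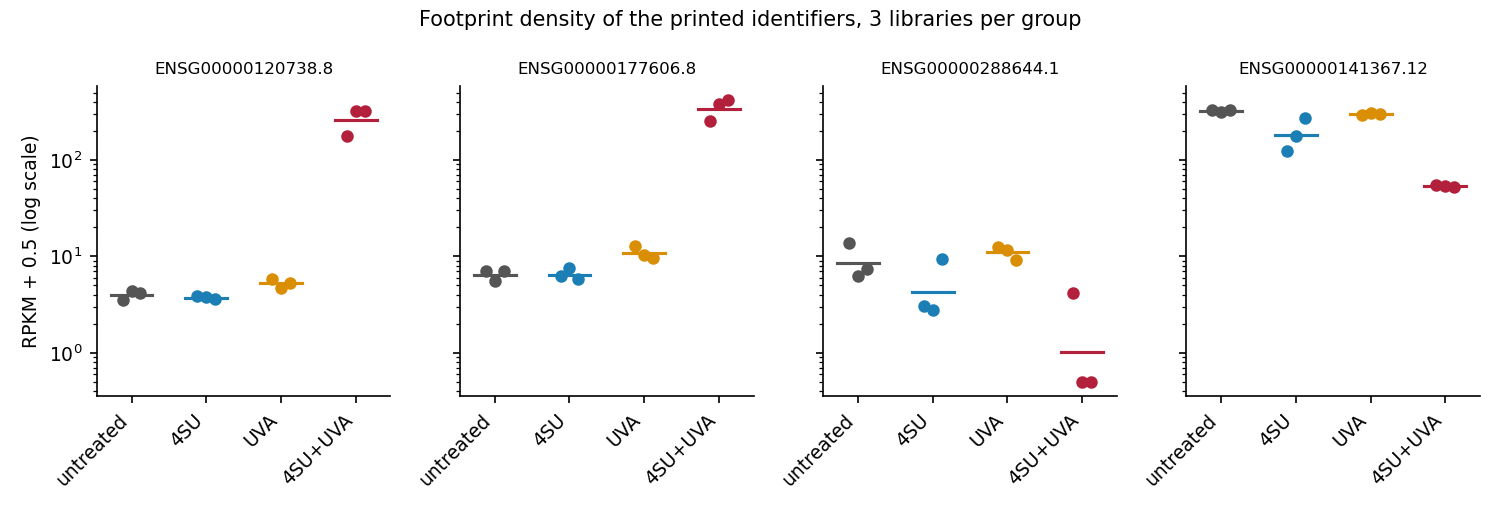
Footprint density of the 4 printed identifiers (y axis, RPKM + 0.5 on a log scale) in the 4 groups on the x axis; each point is 1 library and each line the mean of the 3 log values. ENSG00000120738.8 and ENSG00000177606.8 reach means of 272 and 349 RPKM with 4SU+UVA, and ENSG00000141367.12 falls to 53.4 RPKM there while its 4SU libraries spread from 125 to 274 RPKM.

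Long transcripts fell mainly where they were abundant, and most short transcripts that passed the test rose. Genes were divided into 5 equal classes by transcript length and 5 by mean RPKM over the 12 libraries, a division chosen after the table had been seen. Among the 109 genes in both the longest class (4669 to 28227 nt) and the most abundant one, 88 fell and 11 rose, with a median log2 change of -0.78, or -1.01 relative to the median gene (limma camera, adjusted p = 7.8e-31, and adjusted p = 0.028 with an estimated correlation). Of the 2302 genes in the shortest class (42 to 1459 nt), 1252 rose and 141 fell, with a median of 0.14 above that of all genes (camera, adjusted p = 9.9e-05, lost at adjusted p = 0.12 with an estimated correlation). The 664 genes in both the longest and the least abundant class went the other way, with 251 higher, 29 lower and a median of 0.10 relative to the median gene (camera, adjusted p = 0.011, lost at adjusted p = 0.26 with an estimated correlation), which turned to a median of -0.09 with 64 higher and 121 lower under quantile normalisation. The longest class as a whole lay at -0.15 relative to the median gene, with 690 higher and 627 lower genes (camera, adjusted p = 0.0021, lost at adjusted p = 0.20 with an estimated correlation). Its own median of 0.09 turned to -0.11 under median centring, with 394 higher and 816 lower genes, and to -0.22 under quantile normalisation, with 285 and 917. The medians of the 109 long abundant genes (-0.98 and -0.79) and of the shortest class (0.18 and 0.25) kept their signs under both, with 798 higher and 312 lower genes of the shortest class under median centring and 997 and 206 under quantile normalisation.

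**Figure D3:**
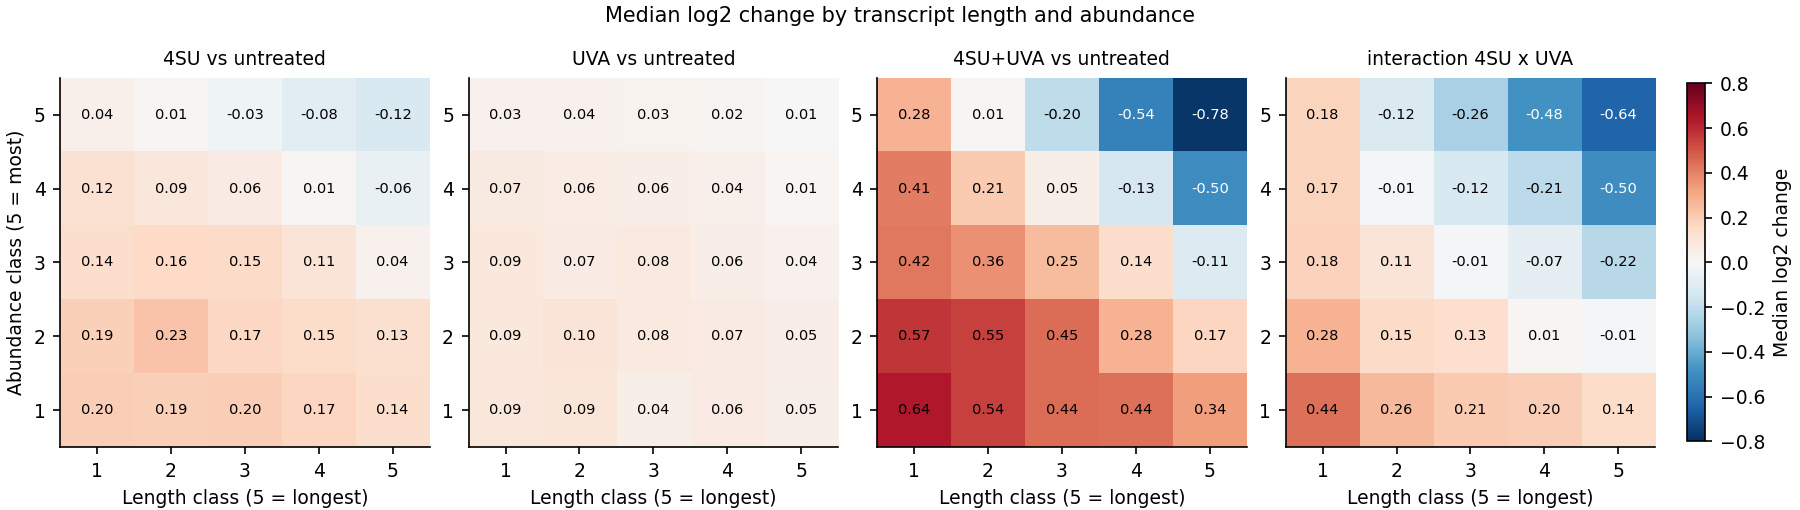
Median log2 change of footprint density (colour and printed value) by 5 classes of transcript length (x axis) and 5 of mean abundance (y axis) for 4SU alone, UVA alone, both, and their interaction, with the deposited scaling. With both treatments the medians run from 0.64 at short, scarce transcripts to -0.78 at long, abundant ones; in the UVA panel they lie between 0.01 and 0.10.

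Per library, the slope of log2 density on log2 length, taken on each gene's difference from its mean over the 12 libraries, gave the same contrast. It averaged 0.039 ± 0.0072 per doubling of length in untreated cells and -0.0985 ± 0.0254 with 4SU+UVA (SD, n = 3 each), where it fell by 0.138 (exact two-sided permutation test, p = 0.1, the smallest possible). The 3 4SU+UVA libraries, from -0.128 to -0.0813, all lay below the other 9. In the most abundant class of genes the means were 0.0882 ± 0.0093 and -0.228 ± 0.0087.

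**Figure D4:**
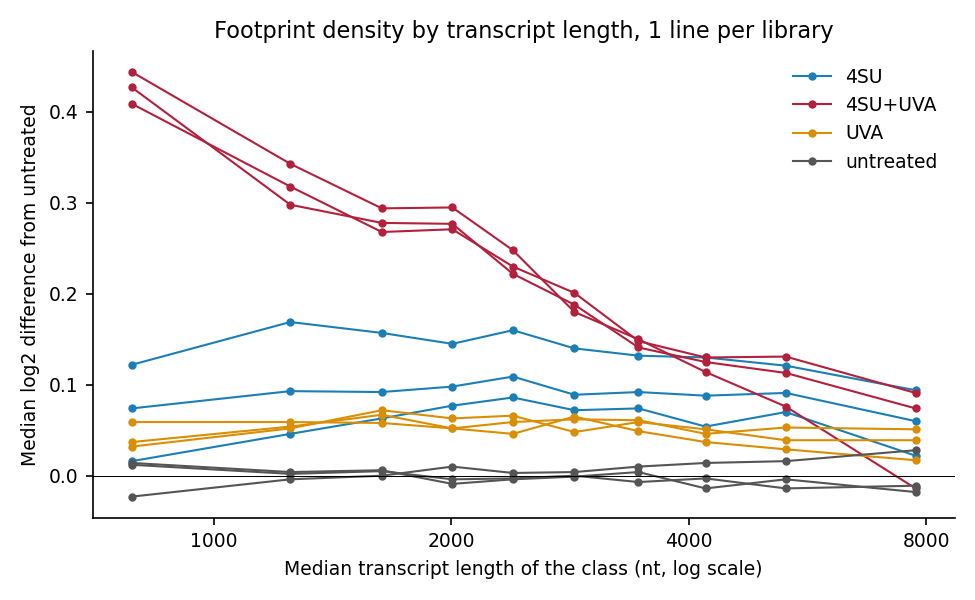
Median log2 difference from the untreated mean (y axis) in 10 equal classes of transcript length (x axis, median length in nt on a log scale), 1 line per library, each untreated library set against the other 2. The 4SU+UVA libraries lie at 0.409 to 0.444 in the shortest class and at -0.014 to 0.091 in the longest, with the deposited scaling.

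What the nucleoside does without light was asked by comparing 4SU alone with untreated cells. Here 1295 genes were higher and 359 lower (limma, n = 3 per group), of which 35 and 3 by at least 2-fold, so the changes were many and small. ENSG00000141367.12 was among the lower genes, at 192 ± 75.8 RPKM (SD, n = 3; log2 -0.82, SE 0.18, limma adjusted p = 0.0087), but its 3 libraries held 125, 178 and 274 RPKM. Of the 109 long and abundant genes, 25 were lower and 3 higher, with a median of -0.22 relative to the median gene (camera, adjusted p = 9.1e-13, lost at adjusted p = 0.29 with an estimated correlation). Median centring gave 52 lower and 2 higher of them, and quantile normalisation 22 and 3. The mean transcript length per read was 3066 ± 31.4 nt (SD, n = 3), a difference of -50.7 nt from untreated cells, and every 4SU library lay below every untreated one (exact permutation test, p = 0.1, the smallest possible). The length slope averaged 0.0285 ± 0.0125, a difference of -0.0106 with overlapping libraries (exact permutation test, p = 0.4). With abundance as a second term, added after the data had been seen, the difference was -0.0354, and the 4SU slopes of 0.0122 to 0.0521 all lay below the untreated ones of 0.0644 to 0.075. Median centring turned the split to 702 higher and 978 lower, and quantile normalisation gave 678 and 497. The number of genes depended on single libraries, with 726 without 4SU replicate 1, 772 without 4SU replicate 2, 2050 without 4SU replicate 3, 1198 without untreated replicate 1, 872 without untreated replicate 2 and 869 without untreated replicate 3. Thinning all libraries to 1898709 reads left 828. The 3 libraries of each group did not overlap at 35.3% of genes, where regrouping gives 10% on average, an excess that was not tested.

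UVA alone changed few genes, and those that fell were short and densely covered by footprints. Against untreated cells, 32 genes rose and 43 fell (limma, n = 3 per group), with 14 and 1 of them by at least 2-fold. Groups did not overlap at 16.8% of genes, where regrouping gives 10% on average, an excess that was not tested. The 43 that fell had a median transcript of 503 nt, 39 of them under 1500 nt, and a median density of 3240 RPKM, with 37 over 500 RPKM. Their footprints took 7.42 ± 0.031% of reads in untreated cells, 5.65 ± 0.138% with UVA, 7.49 ± 0.265% with 4SU and 10.5 ± 0.473% with 4SU+UVA (SD, n = 3 each). Their median log2 change was -0.46 with UVA alone (-0.51 under median centring and -0.18 under quantile normalisation) and 0.49 with UVA in cells that carried 4SU. The 32 that rose were of ordinary length, with a median of 2172.5 nt, and rose by a median of 0.91 without and 0.89 with 4SU. Their share of reads was 0.105 ± 0.0078% in untreated cells, 0.194 ± 0.0258% with UVA, 0.119 ± 0.0095% with 4SU and 0.22 ± 0.0144% with both (SD, n = 3 each). ENSG00000120738.8 and ENSG00000177606.8 lay at 4.77 ± 0.575 and 10.5 ± 1.57 RPKM with UVA alone, changes that did not pass (log2 0.39 and 0.75, limma adjusted p = 0.59 and 0.087). The UVA count was sensitive to settings, with 45 genes when no filter on low values was used, 42 under quantile normalisation (22 higher and 20 lower) and 27 without the variance trend, and none of the 14 length and abundance classes passed (camera, lowest adjusted p = 0.46). Mean transcript length per read was 3161 ± 18.5 nt with UVA (SD, n = 3), a rise of 43.9 nt from untreated cells. Every UVA library lay above every untreated one (exact permutation test, p = 0.1, the smallest possible).

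**Figure D5:**
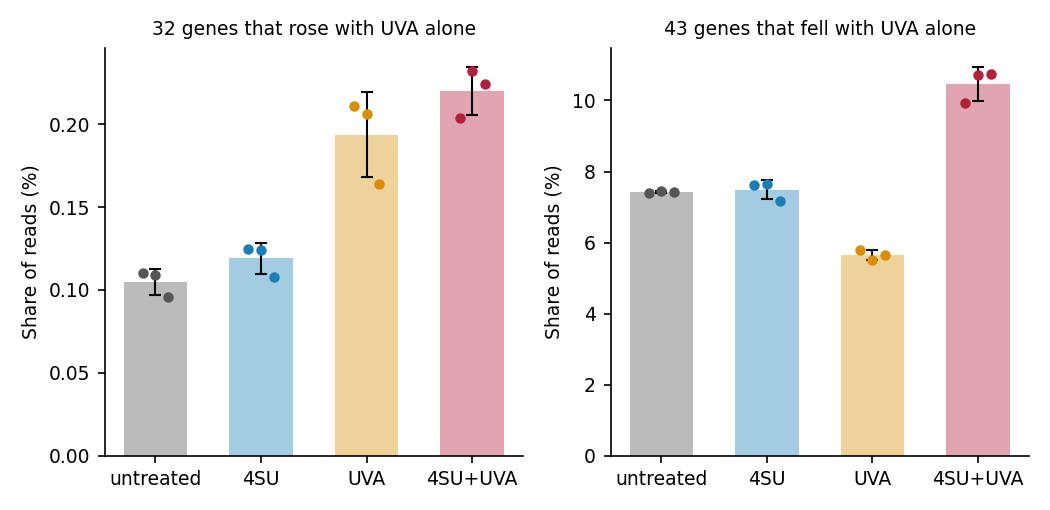
Share of all reads (y axis, percent) taken by the 32 genes that rose and the 43 genes that fell with UVA alone, in the 4 groups on the x axis; bars are means, error bars SDs and points the 3 libraries. The 43 genes hold 5.65% of reads with UVA, 7.42% in untreated cells and 10.5% with 4SU+UVA; these sets were chosen on the UVA and untreated libraries.

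The effect of light in cells that carried 4SU came from comparing 4SU+UVA with 4SU. It moved 2877 genes up and 2185 down, with 309 and 166 of them by at least 2-fold (limma, n = 3 per group). Among the 109 long and abundant genes 87 fell and 9 rose, with a median log2 change of -0.67 (camera, adjusted p = 9.7e-26, and adjusted p = 0.048 with an estimated correlation), while in the shortest class 961 rose and 160 fell, with a median of 0.27 (camera, adjusted p = 6.5e-07, and adjusted p = 0.049 with an estimated correlation). Of the 43 genes that fell with UVA alone, 39 rose here and 1 fell, where independent lists over all genes would share 10.7 and 8.2. Of these 43, 37 belong to the shortest and most abundant class, in which 496 of 979 genes rose here and 103 fell, so the number for all genes is too low a reference for them. Of the 32 that rose with UVA alone, 25 rose again and 1 fell, where 8 and 6.1 would be shared. These comparisons have no library in common. As sets, both passed at the preset correlation (camera, p = 3.3e-14 for the 43 and 1.6e-09 for the 32), and with an estimated correlation p = 0.062 and p = 0.046. The 43 depend on the scaling, since 39 still rose under median centring but 16 under quantile normalisation, where their median was 0.05. Median centring gave 2136 higher and 2788 lower genes in this comparison. Groups did not overlap at 51% of genes, where regrouping gives 10% on average, an excess that was not tested.

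The effect of 4SU in irradiated cells came from comparing 4SU+UVA with UVA. It reached 3989 higher and 2278 lower genes, of which 547 and 344 by at least 2-fold (limma, n = 3 per group). The long and abundant genes again fell, 89 of 109 against 9 that rose, with a median of -0.76 (camera, adjusted p = 1.7e-29, and adjusted p = 0.032 with an estimated correlation). Of the 1295 genes that were higher with 4SU alone, 830 were higher here and 39 lower, where independent lists would share 448.8 and 256.3. Of the 359 that were lower, 283 were lower here and 27 higher, where 71.1 and 124.4 would be shared, again with no library in common. These references count all genes and take no account of length or abundance. The 4SU libraries themselves lay at 0.306, 0.262 and 0.155 of the way along the change from UVA to 4SU+UVA, a spread between replicates that enters both this overlap and the lists of 4SU genes. Median centring gave 2680 higher and 3010 lower genes and quantile normalisation 2900 and 2820. Groups did not overlap at 59.4% of genes, where regrouping gives 10% on average, an excess that was not tested.

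Whether the combination exceeded the sum of its parts was tested as an interaction, the UVA effect with 4SU minus the UVA effect without it. It passed at 2857 genes, 1233 above and 1624 below the sum, and 234 and 182 of them by at least 2-fold (limma, 12 libraries). For ENSG00000120738.8 the interaction was 5.74 (SE 0.26, limma adjusted p = 1.2e-08), for ENSG00000177606.8 it was 4.97 (SE 0.25, adjusted p = 1.6e-08) and for ENSG00000141367.12 it was -1.66 (SE 0.25, adjusted p = 0.00031), while ENSG00000288644.1 did not pass at -2.44 (SE 0.92, limma adjusted p = 0.067) unless 4SU+UVA replicate 1 was left out (-3.46, adjusted p = 0.00112, in a range of 0.00112 to 0.161 over its alternatives). Of the 109 long and abundant genes 81 lay below and 5 above the sum, with a median of -0.64 (camera, adjusted p = 1.1e-24, and adjusted p = 0.04 with an estimated correlation). In the shortest class 500 lay above and 99 below, with a median of 0.21 (camera, adjusted p = 2.4e-07, and adjusted p = 0.04 with an estimated correlation). Mean transcript length per read fell by 319.3 nt more than the sum of both parts, which was -10.2 times its standard error (permutation of residuals from the additive model, p = 0.0023, adjusted p = 0.003 over 8 measures tested). Regrouping all 12 libraries, with the difference divided by its standard error, also passed (exact permutation test, p = 0.00054). The undivided difference did not pass (exact permutation test over the same regroupings, p = 0.1). The interaction of the length slope was -0.119, or -6.9 times its standard error (permutation of residuals from the additive model, p = 0.0023, adjusted p = 0.003). Divided by its standard error, it passed when all 12 libraries were regrouped (exact permutation test, p = 0.018). Undivided, it did not pass (exact permutation test over the same regroupings, p = 0.17). These regroupings also move the single effects of 4SU and UVA.

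Across genes, the UVA effect with 4SU correlated little with the UVA effect without it (Pearson r = 0.17, Spearman rho = 0.14 over 11510 genes), whereas the 4SU effects with and without UVA correlated at r = 0.48 and rho = 0.48. The changes in each pair share no library. Genes are not independent replicates, so these values describe the libraries and carry no p. The single effects had an SD over genes of 0.204 for UVA and 0.287 for 4SU, at a median SE of 0.131. Error makes up more of the UVA effects and lowers their correlation more. The gap between the correlations therefore does not show that the UVA response was kept less than the 4SU response.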

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

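Among the tests below, all tests of the length slope, thinning included, and those on the genes changed by UVA alone were chosen only after the results had been seen.

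The response to UVA differed between cells with and without 4SU at 2857 genes by the interaction test. Of 100 regroupings of the 12 libraries, the real one included, 3 called as many genes, a share under 0.05, and the highest other regrouping called 2895. Of the 99 drawn regroupings, the 2 that kept all 3 4SU+UVA libraries in 1 group reached up to 2895, those with 2 of them together at most 1252, and the median was 0, so these counts follow the distance of the 4SU+UVA libraries from all others. The share therefore depends on how often those 3 libraries were drawn together. It cannot exclude chance and gives no separate support to the interaction. For each pairwise comparison, 3 libraries against 3 give 10 splits, of which 1, the real one, called as many genes, and a share under 0.05 is out of reach. The real counts and the highest other split were 6796 and 1 for 4SU+UVA against untreated, 1654 and 0 for 4SU against untreated, 75 and 0 for UVA against untreated, 5062 and 0 for 4SU+UVA against 4SU, and 6267 and 0 for 4SU+UVA against UVA.

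Longer transcripts lost footprints relative to shorter ones when 4SU and UVA were combined, with an interaction of the length slope of -0.119 per doubling of length. Scarce genes under the pseudocount and depth are argued against, because the slope difference between 4SU+UVA and untreated was -0.316 in the most abundant of 5 classes of genes, and -0.143 after all libraries were thinned to 1898709 reads, with every 4SU+UVA library at or below -0.085 and every other at or above 0.0119. With 4SU alone the slope difference was -0.0106 (-0.0036 without 4SU replicate 1, -0.0064 without untreated replicate 1, -0.0354 with abundance as a second term). With UVA alone it was -0.008 (-0.0039 without untreated replicate 1, -0.0048 without UVA replicate 3, -0.0159 with abundance as a second term). These differences were small beside -0.138 for both treatments together. A hypothesis is that crosslinks, which need 4SU and light together, are more numerous on longer mRNAs, but the interaction restates the pattern and any cause particular to the combination predicts it. Crosslinks therefore cannot be told apart from direct damage to RNA, length-dependent losses before RNase I digestion or loss of long mRNA itself. Neither crosslinks nor mRNA levels were measured in these libraries.

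Single identifiers with a different UVA response in the presence of 4SU were ENSG00000120738.8 (interaction 5.74), ENSG00000177606.8 (4.97) and ENSG00000141367.12 (-1.66). Of the 43 genes that fell with UVA alone, 39 rose with UVA in cells that carried 4SU (16 under quantile normalisation), and 42 passed the interaction test, a count favoured by having picked these genes for their fall.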

How the results depend on the processing

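Thinning, voom, every alternative of the length slope and the leaving out of replicates for the correlations were chosen only after the data had been seen. The counts of changed genes in 4SU+UVA vs untreated, 4SU vs untreated, UVA vs untreated, 4SU+UVA vs 4SU, 4SU+UVA vs UVA and the interaction stayed within 1.5 times the reported ones under all settings but those named here. A 2-fold requirement, stricter by construction, left 1070, 38, 15, 475, 891 and 416. Thinning left 828 genes for 4SU vs untreated, where fewer reads were tested. For UVA vs untreated, no filter gave 45, quantile normalisation 42 and no variance trend 27, and the cause was not tested. Leaving out 1 replicate gave 6038 to 6384, 726 to 2050, 52 to 73, 4288 to 4709, 5530 to 5846 and 2335 to 2794 genes, with 4SU vs untreated lowest without 4SU replicates 1 (726) and 2 (772) and untreated replicates 3 (869) and 2 (872). limma voom on recovered reads called 6970, 2350, 100, 5147, 6347 and 3080. The correlation of UVA effects was 0.211 at a minimum of 5 RPKM and 0.141 to 0.177 without 1 replicate, and that of 4SU effects 0.521 at 5 RPKM, 0.443 after quantile normalisation and 0.414 to 0.493 without 1 replicate. The length slope of 4SU+UVA vs untreated was -0.177 at 5 RPKM, -0.221 with abundance as a second term and -0.146 to -0.123 without 1 replicate, and its interaction -0.157, -0.170 and -0.128 to -0.104. The cause of these shifts was not tested. Of 132 alternatives for the printed identifiers, 131 kept direction and side of the threshold, 0 reversed, and the interaction of ENSG00000288644.1 passed without 4SU+UVA replicate 1 (-3.46). Same-numbered replicates did not deviate together (r -0.046 to 0.068, 0 of 18 pairs over 0.1, 5 of 12 libraries closest to their own number), and a replicate block gave 6818, 1612, 76, 5045, 6223 and 2790 genes. The gene list tests and their alternatives were not run, since no identifier could be matched to a symbol. Depth limits ENSG00000288644.1, with 2 reads in 3 libraries, and 4SU+UVA replicate 2, the shallowest at 1899854 reads.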

Other observations

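All tests described here were chosen only after the data had been seen.

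The 10 genes with most reads over all 12 libraries together took a larger share of reads after the combined treatment. This fixed set held 5.18 ± 0.085% of reads in untreated cells, 5.02 ± 0.0917% with 4SU, 4.65 ± 0.0751% with UVA and 6.18 ± 0.262% with 4SU+UVA (SD, n = 3 each). The combination exceeded the sum of its parts by 1.69 percentage points (permutation of residuals from the additive model, p = 0.0023, adjusted p = 0.003 over 8 measures). In the least abundant of 5 classes 896 genes rose, 64 fell and 1342 did not pass with 4SU+UVA against untreated, with a median log2 change of 0.22 relative to all genes (limma camera, adjusted p = 0.0021, lost at adjusted p = 0.082 with an estimated correlation), and the class held 566 higher and 133 lower genes with a median of 0.25 under median centring, but 306 and 274 with a median of 0.04 under quantile normalisation. In the 324 genes that were both short and scarce, 122 rose and 6 fell, with a median of 0.64 (87 and 10 with a median of 0.44 under median centring, 56 and 16 with a median of 0.23 under quantile normalisation, camera adjusted p = 0.04, lost at adjusted p = 0.18 with an estimated correlation).

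The 3 libraries given 4SU alone had moved by different amounts along the change that separates 4SU+UVA from UVA, at 0.306, 0.262 and 0.155 of its length for replicates 1, 2 and 3, while the untreated libraries lay between -0.007 and 0.008. Depth is argued against, as the range of the 3 positions was 0.151 with all reads and 0.141 after thinning. Reads of 4SU+UVA libraries mixed into 4SU libraries would need the same share for all genes: genes that rose and fell at least 2-fold needed medians of 29.2% and 40.4% in replicate 1, 25.6% and 31% in replicate 2 and 17.2% and 15.2% in replicate 3, which left mixing possible. A further test, added once those shares were known, argued against mixing as the whole cause, since the 39 genes that rose at least 4-fold needed medians of 9.6%, 4.6% and 4.3% (upper quartiles 19.9%, 14.4% and 12.5%), against medians of 30.4%, 27.4% and 18.1% for the 696 that rose 2-fold to 4-fold. Some activation of 4SU by light during culture or handling may remain as an explanation, as may a difference between cultures, and neither was tested.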
